A study of Mus musculus with 16 samples.

How the data were processed

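Total RNA of macrophages grown from bone marrow with macrophage colony stimulating factor was measured on single-colour, biotin-labelled Illumina mouse arrays, per the labels' protocols. The deposited table held, for each of 16 arrays, a mean bead intensity per probe that was not background-subtracted and not normalized between arrays, per the file headers and the values. It also held a detection p-value per probe and array, per the file headers, which is the share of negative-control probes brighter than the probe, in steps that imply 798 such probes. GenomeStudio is named in the submitters' processing notes, and its version and settings are not given in the sources used here. The authors' series-matrix values are intensities on a linear scale, with column medians between 11.2 and 11.3 and lowest values between -23.3 and -18.0, so a background had been subtracted and the columns brought to a common distribution. They are not log values and not centred per gene, and the exact normalization is unknown. Each matrix column had a rank correlation of 1 with the raw signals of its own array and of at most 0.917 with another array, and it was used as an alternative source of values.

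Of 25697 probes, 23978 had 1 gene symbol in the platform annotation, 0 had several and 1719 were not listed there and are given by probe identifier. For 23962 probes the symbol was looked up through its Entrez identifier, which changed 0 symbols. Probes of Ndst1, Soat2 and Ddx3y were not analysed here. No genome was used, and no coordinates are given.

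Signals were processed with limma 3.58.1 (with statmod 1.5.0) in R 4.3.3. The neqc function corrected the background from the negative-control signal inferred from the detection p-values, added an offset of 16, normalized between arrays by quantiles and took log2. A probe was kept when its detection p was under 0.01 on at least 4 of the 16 arrays, which left 10224 probes. The probe detected on most arrays, and then the brightest, stood for its gene, which gave 7082 named genes and 565 unnamed probes. Of 1881 genes with more than 1 kept probe, 825 had any probe called between mouse numbers, 327 had every probe called, and 12 had probes called in opposite directions. Between duplicate numbers these counts were 1129, 570 and 8. A probe detected on none of the arrays of a side has only a bound there, given as at least N-fold: the mean of the other side against the mean of, per array, the higher of its own value and the lowest value of a detected probe, and no size is given where this is under 1-fold. Where few arrays of a side detected a named gene, the text says how many. The arrays had a background median between 129 and 141 and a raw median between 148 and 161, and 36.0% to 39.4% of the probes were detected.

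Samples were grouped by the genotype and treatment in the labels. The 2 arrays of a mouse and treatment were averaged, and the 8 averaged values per gene were fitted with the group as the only term (lmFit, contrasts.fit, eBayes), with 4 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. The labelled comparisons were agLDL against untreated under each genotype label, Ndst1-deficient against wild-type without and with agLDL, and their interaction. The design, the gene lists, the rule for named genes and the alternatives of the labelled comparisons were chosen before the data were examined.

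On each slide lay the arrays of 1 genotype label, so the slide could not enter the model. Untreated arrays took positions A to D and agLDL arrays positions E to H on both slides. Arrays of the same mouse and duplicate number took the same pair of positions on both. The numbers come from the labels, and same-numbered mice of the 2 genotypes are different animals. Whether the numbers pair the arrays was checked by the correlation of deviations from the group means. All 24 pairs of the same number had a correlation between 0.468 and 0.830, and every array correlated best with its own number. Over the 8 averaged values, arrays of the same mouse number correlated between 0.589 and 0.772. The numbers were therefore used as a block on the 16 arrays, with 9 residual degrees of freedom, as an alternative added after seeing the data. The comparisons of mouse number, of duplicate number and of their interaction were also added then, with the group as a term on the 16 arrays.

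Of 31 gene lists, 26 had at least 3 measured members. They cover type I interferon and interferon gamma responses, cholesterol and fatty acid synthesis, LXR targets, lipid droplets, lipoprotein receptors, chemokines, NF-kB genes, alternative activation, NRF2, stress response, cell cycle, heparan sulfate and proteoglycans, lysosome, MHC class II, hypoxia, immediate early genes, ribosomal proteins, the Lyz2 locus, macrophage and osteoclast genes, and markers of neutrophils, dendritic, T and NK, B, mast, erythroid and stromal cells and of sex. Lists were tested with camera (preset correlation 0.01), again with an estimated correlation, and with fry, each adjusted over the 26 lists. Camera compares a list with all other genes. Fry asks whether its members move, on balance, one way. With an estimated correlation, the calls that held were type I interferon and stromal genes between mouse numbers and the stress response genes between duplicate numbers. Of the 3 stromal genes tested, Sparc and Col1a1 passed the detection filter only through arrays of mouse number 1.

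The genes named were, per comparison, up to 10 rising and 10 falling most among those past the threshold with the same sign in both mice, or in all 4 groups for the number comparisons. Where fewer than 5 passed, the 5 of smallest p on each side are given as values. For the interactions up to 10 of smallest p were named. Up to 4 members of smallest p were named per list, and Ndst1, Lyz2, Soat2, Xist and Ddx3y were to be given in every sample. Of those, Xist read 6.65 ± 0.21 and 6.65 ± 0.11 (probe ILMN_3123341, log2, SD over 2 mice) in untreated macrophages labelled wild-type and Ndst1-deficient, and 6.68 ± 0.05 and 6.61 ± 0.02 with agLDL.

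The fits were tested on simulated data of 7647 genes with 50 genes changed per fold size. For the agLDL effect in arrays labelled Ndst1-deficient, the fit of the 8 averaged values recovered 12% at 1.5-fold, 46% at 2-fold, 94% at 4-fold and 94% at 8-fold. With the number as a block the shares were 82%, 96%, 100% and 100%, and with no number differences simulated the averaged fit gave 68%, 90%, 100% and 100%. For the interaction the averaged fit recovered 0%, 30%, 76% and 86%, and the blocked fit 48%, 92%, 100% and 100%. The mouse number comparison recovered 92% at 1.5-fold and 100% at each larger fold. With no gene changed, the agLDL effect in arrays labelled wild-type gave 0 calls, and 1 with the number as a block, and the duplicate number comparison gave 0. In the simulated list test, 1 shifted list was called by each test and 0 of 25 others. The simulated noise was independent between genes and between arrays. The list test therefore could not show false calls that come from correlated genes. The recovered shares leave out any spread that arrays of one mouse share beyond the number differences.

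The alternatives were no background correction, an offset of 50, median scaling, the series-matrix values, no filter or detection on all 16 arrays, every probe on its own, each array as a replicate, random and fixed blocks, only the 2 groups compared, an intensity trend with robust moderation, a threshold of 1.5-fold besides the adjusted p, and leaving out each mouse and each array.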

Results

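Bone marrow derived macrophages of 12 week old C57BL6 mice were profiled on 16 single-colour Illumina mouse expression arrays. Ndst1 encodes an enzyme that sulfates the growing heparan sulfate chain, and in the deficient mice its floxed gene is deleted in myeloid cells by Cre expressed from the Lyz2 locus (LysMCre). Macrophages carrying the label wild-type or Ndst1-deficient were kept untreated or were given 50 µg/ml aggregated LDL (agLDL), which loads macrophages with cholesterol, for 24 hours. By the numbers in the labels, each genotype label held 2 mice, each mouse gave macrophages for both treatments, and each mouse and treatment was hybridised to 2 arrays, so 4 mice in all gave 4 arrays each. In the labels an array carries a mouse number and a duplicate number, written here as 1.1, 1.2, 2.1 and 2.2. The arrays detected between 9241 and 10115 probes, and their raw 75th percentile signal lay between 312 and 386. With 2 mice per group, the number of mice limits the precision, and p-values over the 16 arrays measure a spread that is partly technical, because 4 arrays share a mouse.

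The arrays resembled each other by mouse and duplicate number rather than by genotype or treatment. For all 16 arrays the nearest array carried the same number in another group, and for 0 arrays did it lie in the same group. The number accounted for 67.9% of the variance over all genes, against 20.0% by chance for a label of 4 levels, and the group accounted for 10.99%. Genotype accounted for 5.46% and treatment for 3.38%, each against 6.67% by chance. Arrays of the same number in different groups differed by a root mean square of 0.288 ± 0.058 on the log2 scale (SD, 24 pairs). The duplicate arrays of one mouse and treatment differed by 0.468 ± 0.051 (SD, 8 pairs).

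**Figure D1:**
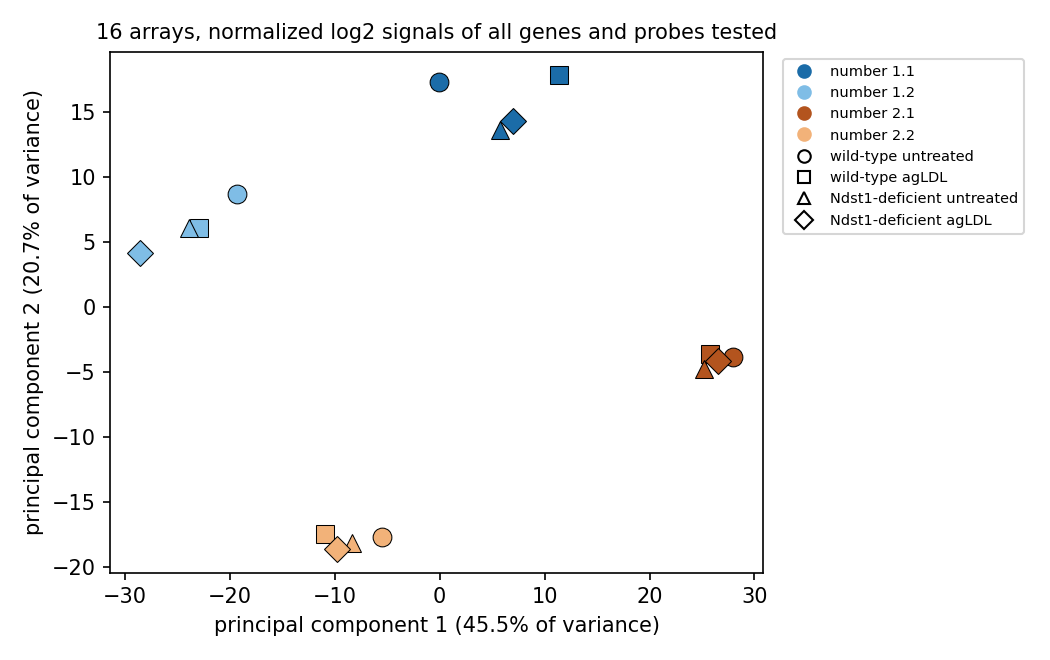
Principal components 1 and 2 of the normalized log2 signals, with 1 point per array, colour for the mouse and duplicate number and shape for the labelled group. The 4 arrays of each number lie together, and component 1 holds 45.5% of the variance.

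**Figure D2:**
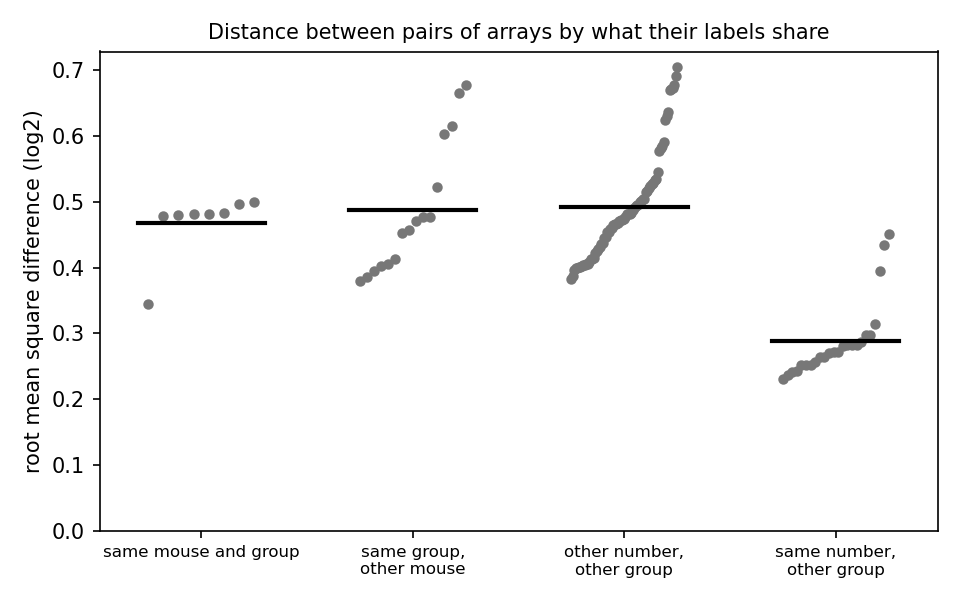
Root mean square log2 difference of every pair of arrays, by what the labels of the pair share, with points for pairs and bars for means. Pairs of the same number in different groups average 0.288, and pairs of one mouse and group average 0.468.

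Lyz2, the lysozyme gene that carries the Cre insertion, served as the check of the genotype labels, since no probe of Ndst1 was analysed here. The Lyz2 probe ILMN_2939681 read 12.51 ± 0.90 in untreated wild-type and 12.44 ± 0.96 in untreated Ndst1-deficient macrophages (log2, SD over 2 mice). With agLDL it read 12.55 ± 0.82 and 12.52 ± 0.76. The difference between the genotype labels was -0.07 without agLDL and -0.03 with agLDL, and with the number as a block the 95% intervals were -0.25 to 0.11 and -0.22 to 0.15. By number, the same probe read 12.05 ± 0.12 on arrays 1.1, 11.75 ± 0.10 on 1.2, 13.40 ± 0.06 on 2.1 and 12.83 ± 0.10 on 2.2 (SD, 4 arrays each). Lyz2 was 2.32-fold higher on arrays of mouse number 2 than of mouse number 1 (limma adjusted p = 1.3e-08). The dimmer Lyz2 probe ILMN_2766780 was 3.69-fold higher (limma adjusted p = 1.3e-07). Between the genotype labels it differed by -0.54 without agLDL and by 0.15 with agLDL, and it was detected on 3 of the 4 untreated arrays labelled Ndst1-deficient. Its 95% intervals were -2.96 to 1.89 and -2.27 to 2.58 over the averaged values. With the number as a block they were -0.90 to -0.17 and -0.21 to 0.52 (limma, blocked adjusted p = 0.176 and 0.883). The third probe, ILMN_1252076, had raw means of 38018 or more in every set, near the top of the scale, and differed by 0.05 on the log2 scale (limma adjusted p = 0.422). Both unsaturated probes differed by more between mouse numbers than between genotype labels, so the samples are named below as arrays labelled wild-type or Ndst1-deficient, and every direction between genotypes rests on those labels.

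**Figure D3:**
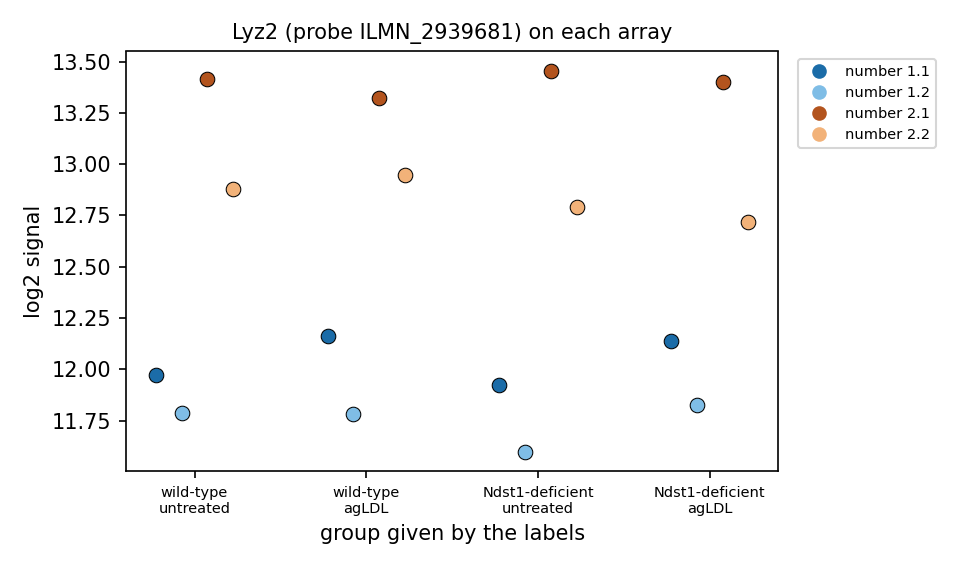
Log2 signal of the Lyz2 probe ILMN_2939681 on each of the 16 arrays by labelled group, with colour for the mouse and duplicate number. In all 4 groups the arrays of mouse number 2 lie above those of mouse number 1, by 1.22 on average.

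The agLDL comparison within arrays labelled wild-type asks which genes respond to cholesterol loading. Plin2, which coats lipid droplets and is a usual marker of foam cells, differed by 0.35 ± 0.20 (log2 fold change ± SE, 2 mice per group), and was higher with agLDL in 3 of the 4 numbers (-0.06 to 0.80). Dgat1, which makes triglyceride, differed by 0.30 ± 0.12, and the cholesterol exporter Abcg1 by -0.16 ± 0.31. Smpdl3a, a target of the sterol receptor LXR, differed by 0.17 ± 0.17, and the nucleic acid sensor Zbp1 by 0.30 ± 0.11. No gene passed the test: limma called 0 of 7647 at an adjusted p under 0.05, with 45 at an unadjusted p under 0.05 where chance gives 382. That fit, here and in the labelled comparisons below, leaves the differences between numbers in the spread, which lowers such counts. A count under chance is therefore no evidence that agLDL changed nothing. With the number as a block on the 16 arrays, 216 genes had an unadjusted p under 0.05 and 0 passed. That is still under the 382 of chance, so the number differences do not account for the whole shortfall. The blocked count was 749 for agLDL in arrays labelled Ndst1-deficient. It was 1094 and 609 between genotype labels without and with agLDL, and 292 for the interaction. The smallest p belonged to Secisbp2, a selenoprotein synthesis factor (at least 1.05-fold higher, not above background on untreated arrays, adjusted p = 0.9999), Fam229b (0.56 ± 0.16) and Homez (0.45 ± 0.13, detected on 1 of 4 untreated arrays) on the higher side. On the lower side they belonged to the phosphatase Dusp22 (-0.36 ± 0.10), Ppp1r13l (-0.38 ± 0.12) and the cell cycle phosphatase Cdc25a (-0.40 ± 0.13). The lipid droplet genes had a median log2 change of 0.03, LXR targets of -0.01 and cholesterol synthesis genes of -0.04. In these lists 0 members passed over all genes and 0 adjusted over the list alone.

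In arrays labelled Ndst1-deficient, Plin2 differed between agLDL and untreated by 0.47 ± 0.20 and was higher with agLDL in all 4 numbers (0.10 to 1.18; 0.47 ± 0.17 with the number as a block, adjusted p = 0.421). The droplet protein Plin3 differed by 0.37 ± 0.13 and the cholesterol transfer protein Stard3 by 0.67 ± 0.24. Marco, a scavenger receptor, was not above background on untreated arrays and at least 1.04-fold higher with agLDL (adjusted p = 0.99998 over all genes), passing adjusted over its list of 10 alone, and Bst2, an interferon-induced restriction factor, differed by 0.39 ± 0.25. Ssbp1, a mitochondrial DNA binding protein, had the smallest p, at 1.18 ± 0.18, followed by the centriole protein Cep135 and Ankrd13d, which were not above background on untreated arrays (adjusted p = 0.99998 for both). Hexim2 (-0.61 ± 0.14), Ppp2r1b (-0.62 ± 0.14) and the methyltransferase Setd7 (at least 1.12-fold lower, not above background with agLDL, adjusted p = 0.99998) stood on the lower side. Limma called 0 of the 7647, with 236 at an unadjusted p under 0.05 against 382 by chance. With the number as a block on the 16 arrays, a comparison added after the data were seen, Ssbp1 passed (adjusted p = 0.021, limma). No gene passed there when any of 9 of the 16 arrays was left out. Median changes were 0.05 for lipid droplet genes, 0.00 for LXR targets, -0.04 for cholesterol synthesis genes and 0.06 for type I interferon genes, and 0 members of these lists passed. With the number as a block on the 16 arrays, 3 of 15 lipid droplet genes rose adjusted over the list alone, and 0 over all genes.

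The agLDL changes of the 2 genotype labels, which share no array, correlated weakly across 7647 genes and probes (Pearson 0.235, Spearman 0.239), with the same sign for 59.2%. Genes are not independent replicates, so these values carry no p. Over the 5 labelled comparisons, camera called 0 of the 26 gene lists that had at least 3 measured members, and fry called 0. The smallest camera adjusted p was 0.078, for unfolded protein and stress response genes between genotype labels with agLDL (median 0.12, adjusted p = 0.803 with an estimated correlation).

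Between genotype labels without agLDL, Ssbp1 differed by -1.46 ± 0.18 on arrays labelled Ndst1-deficient against wild-type (2 mice per group), and Ankrd13d was at least 1.07-fold lower and not above background on arrays labelled Ndst1-deficient, and neither passed the test (limma adjusted p = 0.376 for both). The repair factor Nhej1 (-0.91 ± 0.16), Fam117b (-0.66 ± 0.11) and Vta1 (at least 1.24-fold lower, not above background on arrays labelled Ndst1-deficient, adjusted p = 0.876) followed. On the higher side stood the splicing protein Acin1 (0.70 ± 0.17), Phrf1 (0.61 ± 0.15), the ribonuclease Rexo2 (0.51 ± 0.13) and the lysosomal channel Mcoln1 (0.49 ± 0.13). Among lipid and interferon genes, Stard3 differed by -0.71 ± 0.24, Plin2 by -0.42 ± 0.20, the lipoprotein receptor Lrp1 by -0.42 ± 0.14, the sterol sensor Insig1 by 0.28 ± 0.11 and the interferon regulator Irf9 by -0.24 ± 0.16. The median was -0.00 for type I interferon genes, 0.01 for heparan sulfate genes and 0.12 for cholesterol synthesis genes. Limma called 0 of the 7647, with 383 at an unadjusted p under 0.05 against 382 by chance. With the number as a block on the 16 arrays, 73 genes passed, 13 higher and 60 lower on arrays labelled Ndst1-deficient. That fit uses the 2 arrays of a mouse and treatment as replicates. The planned mouse block on the averaged values called 1 gene. In the genotype comparisons that block is the mouse number, which pairs different animals of the 2 genotypes. In the fit of the 16 arrays, Ssbp1 (adjusted p = 0.001), the ubiquitin ligase scaffold Cul4a (-0.75 ± 0.10, adjusted p = 0.006) and Clip1 (-0.76 ± 0.11, adjusted p = 0.011) were lower, and Rexo2 was higher (adjusted p = 0.021, limma throughout). Cul4a and Clip1 were chosen after their values were seen. The count of 73 became 5 without the wild-type untreated 2.2 array, 7 without the Ndst1-deficient untreated 1.2 array, and 10 without either the 1.2 or the 2.1 array of untreated wild-type. All arrays of 1 genotype label lay on 1 slide, so genotype and slide cannot be told apart in any genotype comparison.

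With agLDL, the prefoldin subunit Vbp1 differed by 0.84 ± 0.12 on arrays labelled Ndst1-deficient against wild-type (detected on 4 and 1 of 4 arrays), the fatty acid oxidation enzyme Eci2 by 0.63 ± 0.14 and Dcun1d1 by 0.76 ± 0.19 (detected on 3 and 1). The unnamed probe ILMN_1256234 differed by -0.69 ± 0.10, Ankrd13d by -0.66 ± 0.13 (detected on 1 and 3), Fam117b by -0.56 ± 0.11 and the Golgi protein Golga1 by -0.55 ± 0.12. Dgat1 differed by -0.34 ± 0.12, Marco by 0.38 ± 0.15 (detected on 3 and 1), the sterol cyclase Lss by 0.34 ± 0.18 and Zbp1 by -0.18 ± 0.11. Limma called 0 of the 7647, with 201 at an unadjusted p under 0.05. With the number as a block on the 16 arrays, ILMN_1256234 passed (limma adjusted p = 0.005). The unfolded protein and stress response list passed camera there (adjusted p = 0.020), a call that was lost at adjusted p = 0.187 with an estimated correlation. The planned mouse block on the averaged values called 0 genes and 1 list. It does not use arrays as replicates, but it too pairs different animals by their mouse number.

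The interaction asks whether agLDL acted differently under the genotype labels. Ssbp1 (1.34 ± 0.25) and Cep135 and Syt9, both not above background on untreated arrays labelled Ndst1-deficient, had the smallest p on the higher side. The granulocyte factor Cebpe (-0.71 ± 0.19) and the neutrophil protease Prtn3 (-0.80 ± 0.22) had the smallest on the lower side. Limma called 0 of the 7647, with 77 at an unadjusted p under 0.05, and the same 0 with the number as a block.

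**Figure D4:**
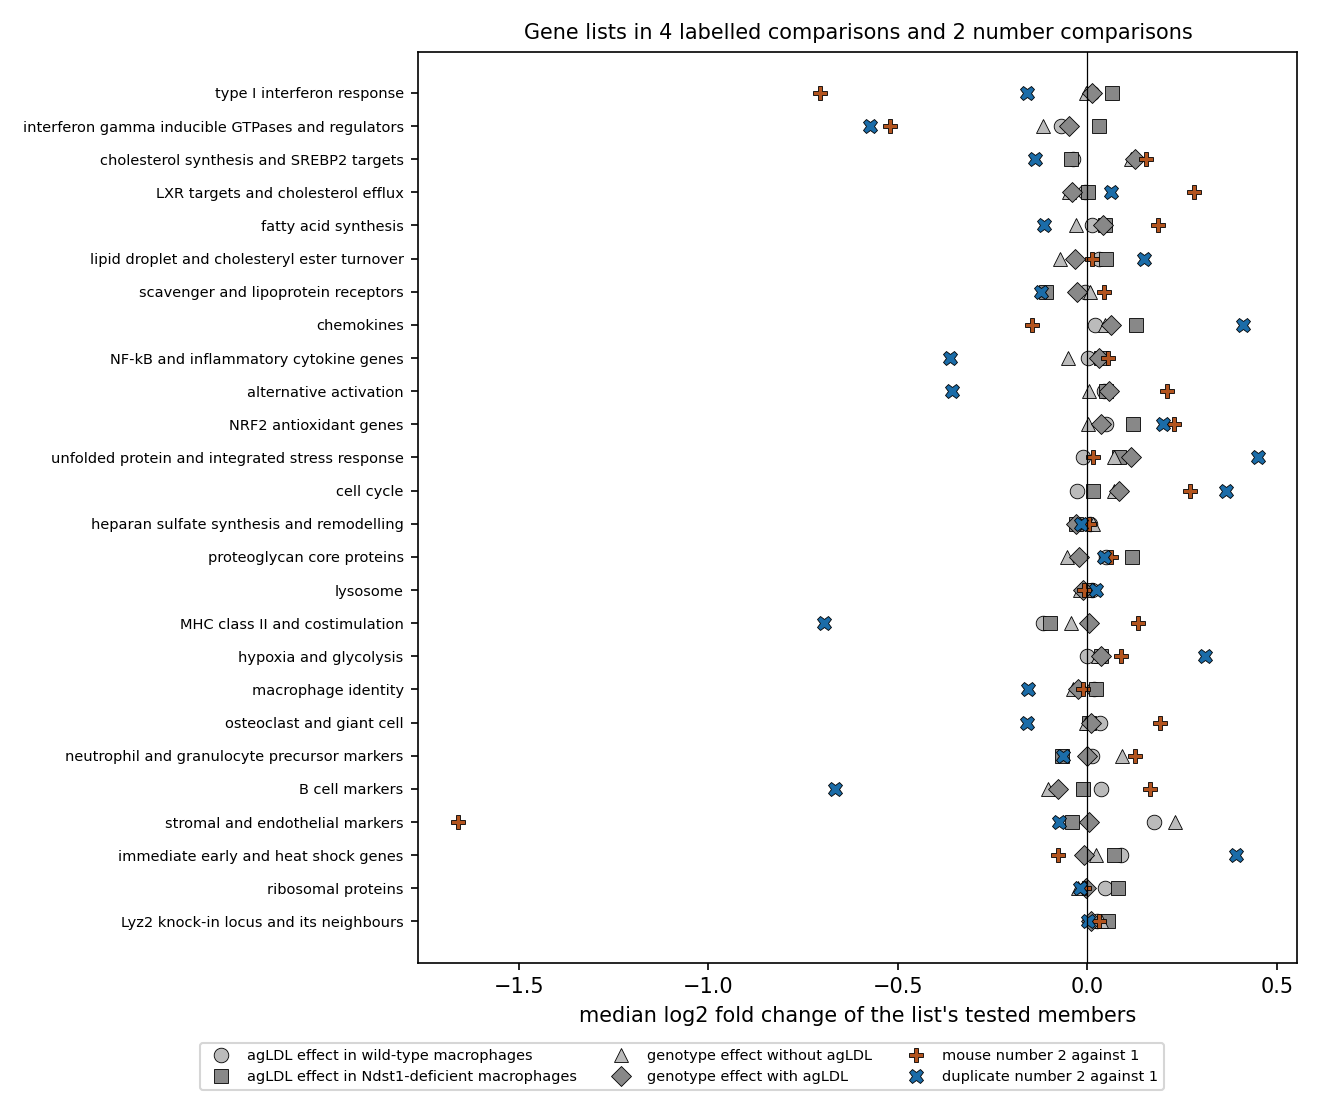
Median log2 fold change of the measured members of each gene list in the 4 labelled comparisons (grey) and the 2 number comparisons (colour). Type I interferon genes lie at -0.71 for the mouse number, and between -0.00 and 0.06 for the labelled comparisons.

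The mouse number and the duplicate number were then compared over all 16 arrays with the labelled group as a term. These comparisons were added after the grouping of the arrays was seen, and the 8 arrays on each side are not 8 independent animals. The monocyte chemokines Ccl8 (-3.61 ± 0.12), Ccl7 (-2.86 ± 0.22, detected on 3 of 8 arrays of mouse number 2) and Ccl12 (-2.65 ± 0.11) and the lymphocyte chemokine Ccl5 (-3.49 ± 0.18) fell on arrays of mouse number 2 (log2 fold change ± SE, 8 arrays against 8). So did the transcription factor Pou3f1 (-2.66 ± 0.09), and the matrix genes Bgn (-2.25 ± 0.09, detected on 1 of 8 arrays of mouse number 2) and Ccn2 (-2.14 ± 0.13). Apol9b and the matrix gene Sparc were not above background on arrays of mouse number 2, and were at least 4.69-fold and 3.53-fold lower there (adjusted p = 2.6e-09 for both). F13a1, the coagulation factor subunit of tissue macrophages, rose by 2.33 ± 0.13, the ion channels Tmem176a by 2.21 ± 0.19 and Tmem176b by 2.16 ± 0.15, and the endothelin receptor Ednrb by 1.71 ± 0.10. The receptor Gpr34 (1.75 ± 0.15), the sulfotransferase Sult1a1 (1.71 ± 0.12), the prostaglandin-degrading enzyme Hpgd (1.68 ± 0.13), the collagen Col18a1 (1.62 ± 0.12) and the kinase Dapk1 (1.55 ± 0.11) rose as well. In all, limma called 2525 of the 7647, 1384 higher and 1141 lower in mouse number 2 (197 and 258 at 1.5-fold or more), and 2391 of them had the same sign in each of the 4 groups.

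Of 35 measured type I interferon genes, 29 fell and 1 rose over all genes, and 30 fell and 1 rose adjusted over the list alone. Among them were the ubiquitin-like modifier Isg15 (-1.68 ± 0.10), the antiviral synthetase homologue Oasl1 (-1.66 ± 0.09), the deconjugase Usp18 (-1.09 ± 0.05) and the viperin gene Rsad2 (-0.89 ± 0.06). The list's median was -0.71, and -0.69 with 1 member at its bound (camera adjusted p = 1.1e-18; adjusted p = 0.016 with an estimated correlation). Of 9 interferon gamma inducible genes 7 fell, such as the GTPases Igtp (-0.93 ± 0.05), Gbp2 (-0.79 ± 0.06) and Irgm1 (-0.52 ± 0.05), while Ciita, the master regulator of MHC class II, went from not above background to detection on 4 of 8 arrays (adjusted p = 1.8e-05). That list's camera adjusted p was 2.2e-04, and adjusted p = 0.195 with an estimated correlation. Of 15 chemokines 7 fell and 2 rose, with a mean of -0.95 and a median of -0.15 (camera adjusted p = 9.7e-04; adjusted p = 0.245 with an estimated correlation). Of 16 stromal and endothelial genes with a probe, 3 passed the detection filter, and all 3 fell. They were Sparc, the smooth muscle actin Acta2 (-1.66 ± 0.09) and the collagen Col1a1, detected on 4 of 8 arrays of mouse number 1 and 0 of number 2 (limma adjusted p = 2.6e-05). Sparc and Col1a1 passed the filter only through arrays of mouse number 1, so their direction was fixed by it. The camera adjusted p of the 3 genes was 6.1e-05, and adjusted p = 0.016 with an estimated correlation. Because of the filter, these values are no independent support for a shift of stromal genes. Of the 3, Acta2, detected on all 8 arrays of each mouse number, was the only one whose direction the filter left free.

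On the higher side of mouse number 2, 9 of 14 NRF2 antioxidant genes rose and 0 fell, with the glutathione enzymes Gsta3 (1.41 ± 0.12), Gstm1 (0.80 ± 0.07) and Gclm (0.54 ± 0.07). Their camera adjusted p was 9.7e-04, and adjusted p = 0.173 with an estimated correlation. Of 24 cell cycle genes 13 rose and 0 fell, such as the centromere histone Cenpa (1.00 ± 0.09) and Birc5 (0.64 ± 0.12), with camera adjusted p = 0.004 and adjusted p = 0.613 with an estimated correlation. Of 8 fatty acid synthesis genes 4 rose, and 6 adjusted over the list alone, with the acetyl-CoA synthetase Acss2 at 0.63 ± 0.11 and the desaturase Fads1 at 0.49 ± 0.07. Camera gave adjusted p = 0.019, and adjusted p = 0.2496 with an estimated correlation. Of 13 LXR targets 7 rose, among them the apolipoproteins Apoc1 (0.55 ± 0.08) and Apoc2 (0.58 ± 0.09), and Nr1h3, which encodes LXR alpha itself, fell by 0.53 ± 0.06. Camera gave adjusted p = 0.035, and adjusted p = 0.391 with an estimated correlation. Of 9 alternative activation genes 5 rose, with the lectins Clec7a (0.51 ± 0.09) and Mgl2 (0.51 ± 0.10), at camera adjusted p = 0.041 and adjusted p = 0.301 with an estimated correlation. Lipid droplet genes had a median of 0.01, with 1 of 15 higher and 2 lower, and 0 of 28 ribosomal protein genes changed.

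**Figure D5:**
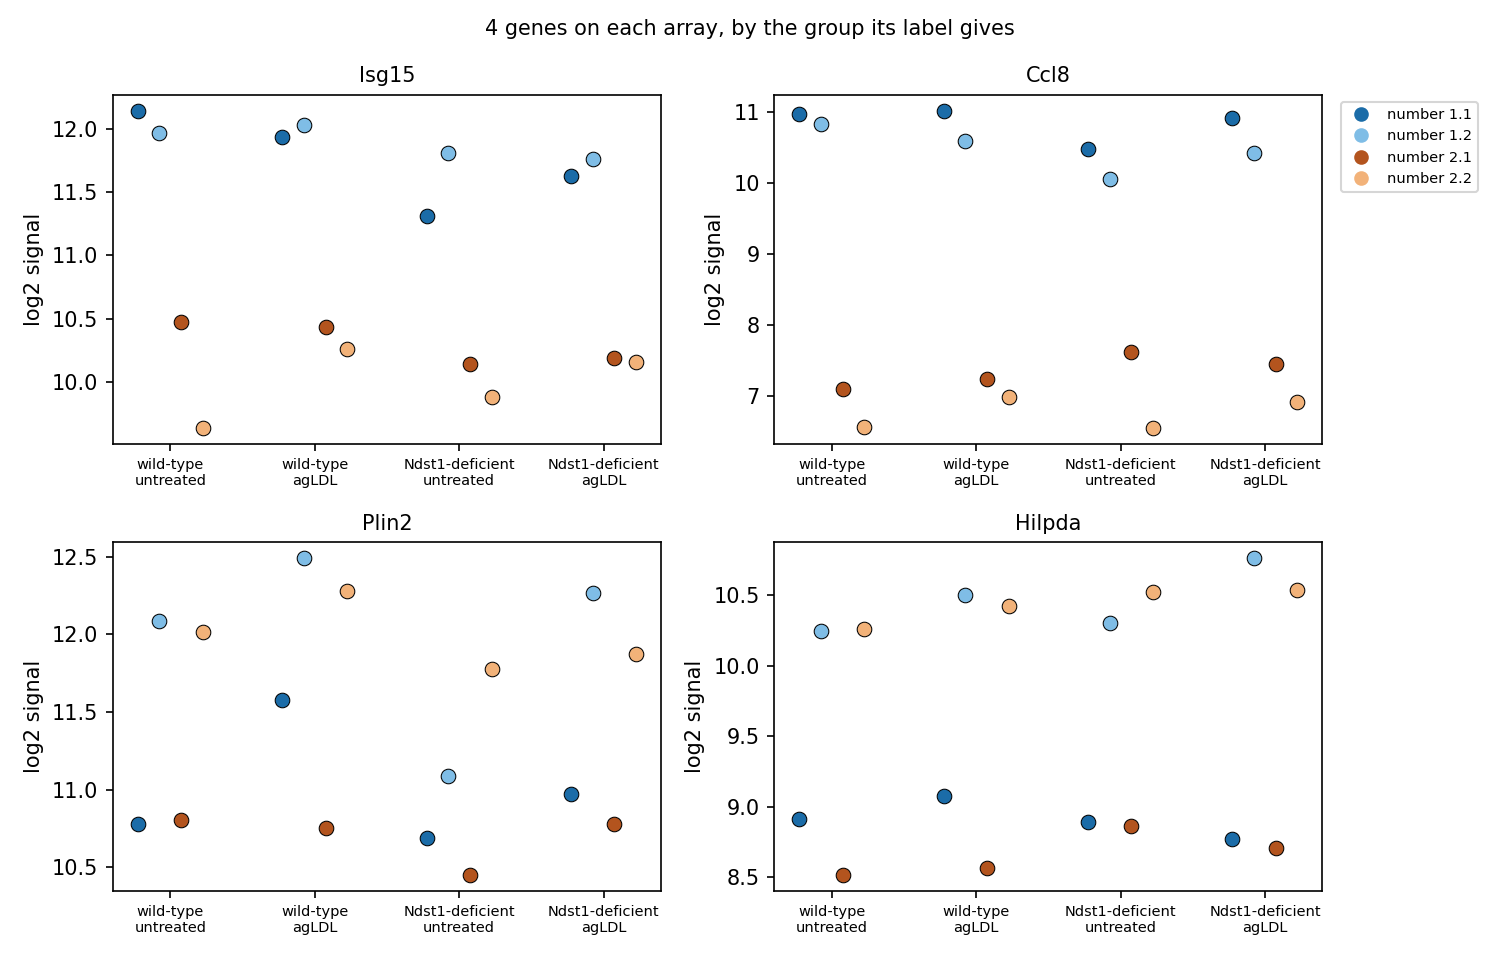
Log2 signals of Isg15, Ccl8, Plin2 and Hilpda on each array by labelled group, with colour for the mouse and duplicate number. Isg15 and Ccl8 differ between mouse numbers by -1.68 and -3.61, and Plin2 and Hilpda between duplicate numbers by 1.13 and 1.66.

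Between duplicate numbers Dusp4, a phosphatase of MAP kinases, rose at least 6.17-fold on arrays of duplicate number 2 from not above background (adjusted p = 4.2e-10). The elastase Mmp12 rose by 2.90 ± 0.14 (log2 fold change ± SE, 8 arrays against 8), the signalling regulator Rgs1 by 2.63 ± 0.11 and the interleukin 1 antagonist Il1rn by 2.45 ± 0.08. Spsb4 (2.44 ± 0.09), the plasminogen activator Plau (2.14 ± 0.16) and the chemokines Ccl7 (2.06 ± 0.22) and Ccl2 (at least 2.05-fold, detected on 4 of 8 arrays of duplicate number 2 and 0 of number 1, adjusted p = 1.4e-06) rose as well. Tmem176a (-2.49 ± 0.19), Tmem176b (-2.19 ± 0.15), the receptor Gpr18 (-2.04 ± 0.11, detected on 2 of 8 arrays of duplicate number 2) and the amino acid oxidase Il4i1 (-2.02 ± 0.12) fell. Ceruloplasmin (Cp, -1.87 ± 0.14), Fcrls (-1.83 ± 0.11), the fractalkine receptor Cx3cr1 (at least 1.79-fold, not above background in duplicate number 2, adjusted p = 2.5e-06), Gpr34 (-1.78 ± 0.15) and the cytokine Il1b (-1.73 ± 0.23) fell too. In all, limma called 3718 of the 7647, 1765 higher and 1953 lower in duplicate number 2, and 3534 had the same sign in each of the 4 groups. The balance was not stable, since median scaling gave 2020 higher and 1338 lower, and 1.5-fold or more left 466 and 388.

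Of 15 lipid droplet genes 5 rose and 0 fell, among them Hilpda (1.66 ± 0.08), Plin2 (1.13 ± 0.12), the fatty acid carrier Fabp5 (1.09 ± 0.13) and the lipase cofactor Abhd5 (0.43 ± 0.07), and the list as a whole did not pass (median 0.15, camera adjusted p = 0.062; adjusted p = 0.292 with an estimated correlation). Of 13 LXR targets 4 rose, Nr1h3 (0.92 ± 0.06), Abcg1 (0.79 ± 0.11), the LDL receptor ligase Mylip (0.61 ± 0.16, detected on 3 of 8 arrays of duplicate number 1) and Lpcat3 (0.25 ± 0.06), and 2 fell (camera adjusted p = 0.371). Of 15 cholesterol synthesis genes 6 fell and 0 rose, with the sterol carrier Stard4 at -0.74 ± 0.09 (detected on 3 of 8 arrays of duplicate number 2), the regulator Srebf2 at -0.56 ± 0.10, Fdps at -0.43 ± 0.10 and Cyp51 at -0.31 ± 0.08 (camera adjusted p = 0.091). Of 8 fatty acid synthesis genes 1 rose and 3 fell, among them Acss2 (-1.10 ± 0.11) and Fads1 (-0.52 ± 0.07), at camera adjusted p = 0.492. The scavenger receptor Cd36, which takes up modified LDL, rose by 1.09 ± 0.12 (detected on 3 of 8 arrays of duplicate number 1), and in its list of 10 lipoprotein receptors 1 rose and 4 fell (camera adjusted p = 0.360).

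Of 22 unfolded protein and stress response genes 15 rose and 2 fell over all genes, and 17 rose and 2 fell adjusted over the list alone. They included the glutathione-degrading Chac1 (at least 2.07-fold, not above background in duplicate number 1, adjusted p = 3.6e-08), the serine synthesis enzyme Psat1 (1.33 ± 0.12), the chaperone Pdia6 (1.08 ± 0.08, detected on 1 of 8 arrays of duplicate number 1) and the transcription factor Atf4 (0.88 ± 0.07). Camera gave adjusted p = 2.7e-05, and adjusted p = 0.019 with an estimated correlation. All 9 measured MHC class II and costimulation genes fell, with Cd86 at -0.95 ± 0.09, Cd40 at -0.71 ± 0.08 and H2-DMa at -0.69 ± 0.07 (camera adjusted p = 3.7e-05; adjusted p = 0.147 with an estimated correlation). Of 9 interferon gamma inducible genes 8 fell, among them Ciita (not above background in duplicate number 2, adjusted p = 2.1e-05), Gbp3 (-0.83 ± 0.09) and Gbp2 (-0.77 ± 0.06), at camera adjusted p = 2.2e-04 and adjusted p = 0.157 with an estimated correlation. Of 17 macrophage identity genes 8 fell and 1 rose, with Adgre1, which encodes the F4/80 antigen, at -0.55 ± 0.06 and Cd14 at -0.54 ± 0.07. Camera gave adjusted p = 0.035, and adjusted p = 0.147 with an estimated correlation. Of 21 NF-kB and cytokine genes 13 fell and 3 rose, with Socs3 at least 1.22-fold lower and not above background in duplicate number 2 (adjusted p = 2.5e-07), Ier3 at -1.22 ± 0.10 and Nfkbiz at -1.15 ± 0.08, at camera adjusted p = 0.044 and adjusted p = 0.458 with an estimated correlation. Of 15 chemokines 10 rose and 4 fell, with Ccl3 at 0.96 ± 0.07, Ccl4 at 0.88 ± 0.06 and the interferon-induced Cxcl10 at -1.65 ± 0.11 (camera adjusted p = 0.035; adjusted p = 0.386 with an estimated correlation). Type I interferon genes had a median of -0.16, with 12 of 35 lower and 2 higher (camera adjusted p = 0.090).

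Of 13 immediate early and heat shock genes 7 rose with duplicate number 2 and 1 fell, with Egr2 at 1.93 ± 0.12, Dusp1 at 1.04 ± 0.08, Jun at 1.01 ± 0.06 and Fos at 0.75 ± 0.09, at camera adjusted p = 0.022 and adjusted p = 0.195 with an estimated correlation. Of 14 NRF2 genes 9 rose and 1 fell, with the cystine carrier Slc7a11 (detected on 5 of 8 arrays of duplicate number 2 and 0 of number 1, adjusted p = 3.3e-07), Srxn1 at 0.71 ± 0.05 and Hmox1 at 0.56 ± 0.09 (camera adjusted p = 0.011; adjusted p = 0.182 with an estimated correlation). Of 24 cell cycle genes 13 rose and 3 fell, among them the replication helicase genes Mcm2 (1.39 ± 0.14), Mcm3 (1.18 ± 0.15) and Mcm6 (0.91 ± 0.10). Camera gave adjusted p = 0.044, and adjusted p = 0.611 with an estimated correlation. Of 13 B cell markers 4 were measured and 3 fell, such as Cd79b (-0.81 ± 0.07) and Fcrla. Fcrla was at least 1.07-fold lower and not above background in duplicate number 2 (limma adjusted p = 3.0e-06). It passed the detection filter only through arrays of duplicate number 1, so its direction was fixed by the filter. The list's median was -0.67, and -0.31 with 1 member at its bound. Camera gave adjusted p = 0.047, and adjusted p = 0.293 with an estimated correlation.

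The duplicate number difference itself differed between the mouse numbers for 8 genes, 1 higher and 7 lower (limma, 637 at an unadjusted p under 0.05 against 382 by chance). Ccl2 was detected on the 4 arrays of number 1.2 and on 0 of the others (adjusted p = 0.016 for the difference). F13a1 differed by -0.62 within mouse number 1 and by -2.52 within mouse number 2 (difference -1.90 ± 0.25, adjusted p = 0.016). This count was 0 within either slide and within either treatment, where 8 of the 16 arrays remained. Camera called 9 lists for this interaction, 1 higher and 8 lower, and 0 with an estimated correlation, where the smallest adjusted p = 0.062.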

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

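All tests in this part were chosen after the result they bear on was seen.

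Of 56 sets of 4 arrays examined for a value far from the rest, 5 held one, where chance alone flags about 1 in 20, or 2.8 sets. The wild-type agLDL 2.2 array had a raw 75th percentile of 358.8, and the other arrays of its number lay between 340.2 and 343.1. The Ndst1-deficient untreated 1.2 array lay at a mean distance of 0.427 from the other arrays of its number, against 0.259 to 0.286 for the rest of its group and 0.306 to 0.319 for the rest of its number. The Lyz2 probe ILMN_1252076, near the top of the scale, read 15.25 on the Ndst1-deficient agLDL 1.1 array and 15.30 on the Ndst1-deficient agLDL 2.1 array, just under the other arrays of its set.

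The difference between duplicate numbers was not alike in the mouse numbers for 8 genes, by the interaction in limma. It differed by -1.90 for F13a1, -2.59 for Ccl2, 1.14 for Yipf7, -1.35 for Aldoc, -1.58 for Ccl12, -0.77 for Gbp2, -1.51 for Ctsg and -0.84 for Slc30a6. Ccl2 was detected on arrays 1.2 alone and Ctsg on none of 1.1, so their sizes rest partly on background.

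Arrays of the same mouse and duplicate number resembled each other across genotype and treatment labels. With terms for the groups and none for the other number, the mouse number called 1018 genes and the duplicate number 2914. Of 100 splits of the 16 arrays into 8 and 8, the real ones included, 2 and 1 gave as many. Counts this large were thus rare among splits, which argues against chance and does not exclude it. The highest other splits gave 1546 and 1838, and in the former 6 of 8 arrays on a side shared the mouse number and 6 of 8 the duplicate number, so its count points to the same structure. The counts did not hinge on the normalization used, since over other background, offset, scaling and matrix settings the lowest was 0.859 of the reported one. All these settings still brought the arrays to a common level, so a signal level that differed between numbers stays open. The raw 75th percentile was 345 ± 22 and 343 ± 17 for mouse numbers 1 and 2 (SD, 8 arrays each, exact permutation p = 0.833). For duplicate numbers 1 and 2 it was 336 ± 20 and 353 ± 16 (exact permutation p = 0.085). Differences between individual mice, as labelled, are argued against. The 2 arrays of one mouse and treatment lay further apart than arrays of 2 mice with the same number and treatment, by 0.183 (0.468 ± 0.051 against 0.285 ± 0.047, SD, 8 pairs each). Genotype labels that do not belong to their arrays stay open, since Lyz2, which the Cre insertion is expected to lower, differed by -0.071 between the labels without agLDL with one probe and by -0.539 with a dimmer one, which did not pass (adjusted p = 0.176) and was detected on 3 of the 4 untreated arrays labelled Ndst1-deficient, and a culture, preparation or slide position shared by arrays of one number cannot be told apart from this, because the mouse number differences repeated on both slides (correlation over genes 0.830) and each number kept its pair of positions.

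With the number as a block, 73 genes passed between genotype labels without agLDL. Of the splits of the 8 untreated arrays, 8 part all 4 pairs, too few for a share under 0.05 (the others put both arrays of a number on one side); 1 gave as many and the highest other gave 0. Whether the single array that stood apart, Ndst1-deficient untreated 1.2, was a source stays open. The 73 genes were chosen with it, and such a choice holds their change near its former size whichever array is left out. Over the untreated arrays left out in turn, the median ratio of the changes ran from 0.926, without this array, to 1.036. Without this array 7 genes were called, 6 of them among the 73. The median absolute change went from 0.568 ± 0.109 to 0.532 ± 0.110 (SE). The median adjusted p (limma) went from 0.041 to 0.104, as both a smaller change and fewer arrays would give. A slide difference may contribute and cannot be told apart from the genotype label, since 66 of the 73 had the same sign with agLDL, at a median of 0.462 of the change (quartiles 0.292 to 0.636). For the single genes called with the block for agLDL in arrays labelled Ndst1-deficient and between genotype labels with agLDL, the 8 splits that part all 4 pairs are too few as well (1 gene in the real split and 0 in the highest other, in both).

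The 3 stromal genes tested were higher on arrays of mouse number 1, and Sparc and Col1a1 had passed the detection filter only through those arrays. Whether stromal cells were among the macrophages stays open: 7 probes of Col1a2, Col3a1, Dcn, Lum and Postn, abundant in such cells, were detected on 0 of the 8 arrays of mouse number 1, but Col1a1 was detected on 4 of them and Cxcl12, by 1 of its 5 probes, on 3, and both on 0 arrays of mouse number 2. Of 16 stromal and endothelial genes with a probe, 3 were detected on at least 4 of these arrays. No biological explanation was tested for this pattern.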

How the results depend on the processing

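The number comparisons, the number block and their settings were chosen after the data were seen, and the other alternatives were planned. The agLDL effect in arrays labelled wild-type kept its 0 genes under every setting, and the interaction of genotype and agLDL likewise. Between mouse numbers and duplicate numbers, none of the 56 and 83 named genes reversed under any setting. The top genes among them were chosen for the same sign in all 4 groups, so settings that keep part of the arrays could hardly reverse those. Of the values those named genes took, 1813 of 1866 between mouse numbers and 2673 of 2751 between duplicate numbers kept their side of the threshold. Signal over background limits what was measured, since 36.0% to 39.4% of the probes were detected per array.

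With the number as a replicate block on the 16 arrays, 1 gene passed for agLDL in arrays labelled Ndst1-deficient, 73 between genotype labels without agLDL and 1 with agLDL, and 1 gene list passed with agLDL. With a random block for mouse and treatment added, these genes numbered 1, 56 and 1. The planned mouse block on the averaged values, which is the mouse number in the genotype comparisons, gave 1 gene between genotype labels without agLDL. It gave 1 list with agLDL, and the blocks changed no other call. The block takes the difference between numbers out of the spread by construction, and no other cause was tested; the cause was not tested for the random block.

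With each array as a replicate, and with arrays in a random block, 1 gene passed for agLDL in arrays labelled Ndst1-deficient, 4 between genotype labels without agLDL and 1 with agLDL. Without background correction, 1 list passed for agLDL in arrays labelled wild-type, and the correlation of the agLDL effects was 0.305. It was 0.133 without a filter and 0.301 over probes detected on all arrays. Under median scaling the saturated Lyz2 probe ILMN_1252076 read 0.016 between genotype labels with agLDL. The cause was not tested.

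Under median scaling 2020 genes rose and 1338 fell between duplicate numbers, against 1765 and 1953, and the cause was not tested. At 1.5-fold or more, 455 genes passed between mouse numbers (197 higher and 258 lower) and 854 between duplicate numbers (466 higher and 388 lower); a stricter threshold lowers the totals by construction, and the turn in the balance was not tested. With 8 arrays, on slide 1 the counts were 1130 and 2266, on slide 2 they were 768 and 2024, on untreated arrays 1063 and 1563, and on agLDL arrays 1357 between mouse numbers. An estimated correlation left 2 lists between mouse numbers, 1 between duplicate numbers and 0 for their interaction. Fry called 14 and 20 lists for the first 2, and over probes detected on all arrays 6 lists passed between duplicate numbers. The interaction of the numbers called 32 genes without background correction, 21 with an offset of 50, 5 with series-matrix values, 2 over probes detected on all arrays, 35 with trend and robust moderation, 15 without group terms, and 0 on each slide and in each treatment. The cause was not tested.

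Leaving out each mouse or array from the averaged values gave 0 genes in every labelled comparison. With the number block, leaving out each array gave 5 to 63 genes between genotype labels without agLDL (7 without the Ndst1-deficient untreated 1.2 array), 1 to 2 with agLDL, and 0 to 4 for agLDL in arrays labelled Ndst1-deficient, with 0 for 9 of the 16 arrays. Leaving out each mouse or array gave 1038 to 2731 genes between mouse numbers, lowest without wild-type mouse 2, and 0 to 30 for the number interaction. With each mouse left out, lists passing numbered 0 to 4 for agLDL in arrays labelled wild-type, 0 to 4 and 1 to 5 between genotype labels without and with agLDL, 0 to 2 for the interaction and 7 to 10 between duplicate numbers. With each array left out, the correlation of the agLDL effects ran from 0.057 to 0.276. Among genes that passed in no labelled comparison, Plin2 ran from -0.030 to 0.73, Abcg1 from -0.50 to 0.19 and Cxcl10 from -0.70 to 0.41 for agLDL in arrays labelled wild-type, and Bst2 from -0.66 to 0.083 between genotype labels without agLDL. Lyz2 between genotype labels without agLDL ran from -0.75 to 0.61 (ILMN_2939681), -1.65 to 0.57 (ILMN_2766780) and -0.041 to 0.052 (ILMN_1252076). With agLDL it ran from -0.62 to 0.54 and from -0.76 to 1.07 for the first 2 probes. A left-out array leaves the other number alone for its mouse, and a group left with 1 mouse is assumed to vary like the others.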

Other observations

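The number comparisons and the hypothesis below were chosen after the data were seen, and the gene lists were planned.

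Heparan sulfate genes moved both ways between the numbers. Of 13 measured, 2 rose and 3 fell between mouse numbers, with the linkage enzyme B3galt6 at -0.43 ± 0.07 and the 2-O-sulfotransferase Hs2st1 at 0.37 ± 0.07 (log2 ± SE, 8 arrays against 8). Between duplicate numbers 5 rose and 5 fell, with B3galt6 at 0.85 ± 0.07, the chain polymerase Ext1 at 0.69 ± 0.06 and heparanase (Hpse) at -0.70 ± 0.11, and the list did not pass (camera adjusted p = 0.723 and 0.868). Of 9 proteoglycan core proteins 4 rose and 1 fell between mouse numbers and 3 rose and 2 fell between duplicate numbers. Of 29 lysosomal genes 5 rose and 4 fell between mouse numbers, and 7 rose and 1 fell between duplicate numbers, among them the protease Ctsk (1.15 ± 0.12) and the proton pump subunit Atp6v1h (0.50 ± 0.05), with camera adjusted p = 0.754 and 0.247. Hypoxia and glycolysis genes rose with duplicate number 2, 8 of 13, with Pkm at 0.68 ± 0.07, Mif at 0.68 ± 0.06, the glucose carrier Slc2a1 at 0.56 ± 0.07 and Ldha at 0.42 ± 0.07, while 1 fell (camera adjusted p = 0.022; adjusted p = 0.147 with an estimated correlation).

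Between mouse numbers, 4 of 9 MHC class II and costimulation genes rose and 1 fell, with Cd74 at 0.64 ± 0.08 and H2-Ab1 at 0.64 ± 0.09 (camera adjusted p = 0.084). NF-kB genes split evenly, 6 up and 6 down of 21, with the cytokine Il10 at -0.95 ± 0.09 and Il1rn at -0.86 ± 0.08. Of 4 osteoclast genes 2 rose and 1 fell between mouse numbers and 2 rose and 2 fell between duplicate numbers. Of 13 neutrophil genes 4 rose and 1 fell, and 4 rose and 4 fell. Of 10 genes at and around Lyz2, 1 rose and 3 fell, and 4 rose and 0 fell. Lists with fewer than 3 measured members were not tested as lists. Their members were Batf3 (0.42 between mouse numbers, -0.25 between duplicate numbers) and Bst2 (-0.37 and -0.17) for dendritic cells, Prf1 (0.16 and -0.29, detected on 1 of 8 arrays of mouse number 1) for T and NK cells, Hdc (-0.61 and -0.23) for mast cells, Epor (0.13 and -0.27) for erythroid cells and Xist (0.12 and -0.19) for sex.

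A hypothesis is that the mouse number may follow the presence of the Cre insertion and the duplicate number exposure to agLDL, rather than the labels. It could be read from Lyz2, which was 2.32-fold higher in mouse number 2 and differed by -0.071 between genotype labels without agLDL (ILMN_2939681), while ILMN_2766780 was 3.69-fold higher. It could also be read from the lipid droplet genes Plin2 and Hilpda, which rose with duplicate number 2 by 1.13 and 1.66. Cholesterol synthesis genes had a median of -0.14 with duplicate number 2 and LXR targets of 0.06, and neither list passed. Hypoxia and glycolysis genes rose with the same number (median 0.31). Lyz2 also differed with duplicate number 2, by -0.43 and -0.71 with these probes (limma adjusted p = 6.7e-05 and 3.0e-04). It thus followed more than the mouse number, and is a weaker sign of the insertion unless agLDL itself lowers Lyz2. With agLDL as labelled, these probes differed by 0.04 and -0.12 in arrays labelled wild-type, without passing. In arrays labelled Ndst1-deficient they differed by 0.08 and 0.57, again without passing. The neighbouring Lyz1 was 1.92-fold lower in mouse number 2 with the probe ILMN_1247933. Its probe ILMN_2736867 was lower too (limma adjusted p = 5.6e-08), detected on 4 arrays each of 1.1 and 1.2 and on 0 of 2.1 and 2.2. With ILMN_2878071, whose raw means were 23600 or more in every number, Lyz1 was 1.16-fold higher. How the Cre insertion acts on Lyz1 was not tested, so Lyz1 is counted neither for nor against the first part. Against the first part, the Lyz2 probe ILMN_2766780 differed between genotype labels by -0.539 without agLDL and by 0.151 with it. Neither difference passed (limma, blocked adjusted p = 0.176 and 0.883), and the probe was undetected on 1 of the 4 untreated arrays labelled Ndst1-deficient. Against the second part, Plin2 differed with agLDL as labelled by 0.35 and 0.47 in the same direction without passing, and the lipid droplet list did not pass between duplicate numbers. No array was moved to another group, and an independent genotype of each sample would bear on the first part and its lipid content on the second.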
